A study of Mus musculus with 40 samples.

How the data were processed

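RNA was extracted from adipose tissue of C57BL/6J mice with an RNeasy kit and sequenced from NEBNext Ultra libraries, per the labels. The 40 libraries were grouped by the depot and treatment that the labels give, 5 libraries in each of 8 groups. The labels name the treatments normal, normal with drug, high-fat diet and high-fat diet with drug; the series description names the drug as beta-carotene. Groups were kept as labelled throughout, and libraries are named by their group and the number in their title. The labels do not say that each library came from a separate animal, so every p-value measures only the spread between these libraries.

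The deposited table holds values in TPM (reads per base of gene length, scaled by the authors so that each library has the same total). The unit was read from the values, since all libraries had the same total. Low values were multiplied by the exon length of their gene. The product that the largest number of genes shared, within a tolerance of 0.2%, was taken as the step of 1 read in a library. Whether other products fell on whole multiples of that step was not tested. The processing notes of the submitters name FastQC 0.11.9, STAR 2.7.8, featureCounts 2.0.3, DESeq2 1.32.0 and genome build GRCm39; they state neither the annotation nor the filters. The same steps gave an approximate number of counted reads per library, 4.58 to 8.59 M (M, 1e6). These numbers are approximate and were used only to describe depth. Values of genes with few reads are imprecise at this depth, which the filter on low values below takes into account. The gene annotation at hand was GENCODE M21 for build GRCm38, which is not the build the submitters name; only exon lengths were taken from it, by gene symbol, for 49067 of the 55270 genes, and no coordinates are given.

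Values were analysed as log2(TPM + 1), a scale that understates the changes of genes with low values. A gene was tested if it reached 10 TPM in at least 5 libraries of the fit. Group means were fitted with limma 3.58.1 in R 4.3.3 (trended and robust empirical Bayes), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The 20 libraries of each depot label were fitted together for the diet and drug comparisons and for the drug-by-diet interaction. All 40 libraries were fitted together for the comparison between depot labels and the depot interactions. A comparison of A with B gives log2 fold changes of A over B with their standard errors (SE), and group values are means with their standard deviation (SD) over 5 libraries.

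Before the data were examined, 39 gene lists were fixed, covering fat cell functions, immune and vascular cell types, matrix, stress and metabolic pathways, depot markers and other tissues that a fat sample can hold. Of their 631 entries, 7 were not in the table, and 32 lists had at least 5 tested members. Lists were tested with limma camera at its preset correlation of 0.01, two-sided, with p-values adjusted over the lists of a comparison. Each call is given with the camera p at an estimated correlation, and counts of members are given over all genes tested and adjusted over the list alone. A list score is the mean of log2(TPM + 1) over the list. Scores were compared between groups with two-sided exact permutation tests, whose smallest p with 5 libraries in each group is 0.0079 (252 permutations).

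The rule for named genes was also fixed beforehand. In each comparison it takes the 6 largest increases and the 6 largest decreases among genes past the threshold whose groups did not overlap and whose mean was at least 100 TPM, leaving out clone names and unnamed genes. It adds up to 3 members past the threshold from each list that passed camera or had at least 3 such members. It always takes Lep, Adipoq, Ucp1, Itgax, Trem2, Ccl2, Adgre1, Fasn, Scd1, Bco1, Bco2, Rarb, Cyp26b1 and Col1a1 in the diet and drug comparisons, and Wt1, Upk3b, Msln, Tbx15, Shox2, Hoxc10 and Ucp1 for the depot check. List members with larger adjusted p-values were left out first to keep about 30 genes per comparison. Genes of this rule that missed the filter are given from the fit with no filter.

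Alternatives fixed before the data were examined were pseudocounts of 0.5 and 5, no filter, a stricter filter, quantile normalization, library weights (limma arrayWeights), a fit of the 2 compared groups alone, a block for shared title numbers, estimated correlations and the fry rotation test for lists, and leaving out each library in turn. Others were added after the values were seen. These were a filter of 1 TPM, removal of mitochondrially encoded genes, a covariate for transcripts of other tissues (the epididymis and testis list for libraries labelled subcutaneous, the B cell list for those labelled visceral), removal of the libraries rich in these transcripts (over 500 and over 1000 TPM in total), and removal of a per-library lowess trend (span 0.3) on exon length, which also centres each library. For HFD with drug against HFD with the label subcutaneous, that trend was also removed with the median of each library kept, and library medians were made equal with no length term. The planned tests on read counts by negative binomial models were not run, since the deposited values are not counts. Random regroupings of the libraries, 100 per comparison, were fitted in the same way. The fits were tested on simulated data with planted changes and noise drawn for each gene apart. For high-fat diet against normal diet in libraries labelled subcutaneous, 72.7% of planted changes of 1 on the log2 scale were called. There 7 of 135 calls were false. For the drug-by-diet interaction with that label, 40.9% of planted changes of 1 were called. Differences that many genes of a library share, as from transcripts of other tissues, were not simulated. False calls from such differences are therefore not covered. Tables, tests of single values and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.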

Results

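Gene expression was measured by RNA sequencing in adipose tissue of C57BL/6J mice, in 40 libraries that fell into 8 groups of 5. The groups combined 2 depot labels, subcutaneous and visceral, with 4 treatments: a normal diet, a normal diet with drug, a high-fat diet (HFD) and HFD with drug. The series description names the drug as beta-carotene, a plant pigment that animals can cleave to vitamin A, and places the visceral fat at the epididymis; the labels give neither the dose nor the duration of diet or drug. The table held TPM for 55270 genes, of which 15340 were at 0 in every library. Counted reads per library were about 4.58 to 8.59 M (M, 1e6). Every library had the same total, so a value is a share of the library and not an amount of RNA per cell. Group values below are means ± SD of 5 libraries in TPM, and changes are on the log2(TPM + 1) scale, which understates changes of genes with low values.

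Markers of the 2 fat depots ran against the depot labels in 40 of 40 libraries, so depots are named below only as "labelled subcutaneous" and "labelled visceral". Genes of the mesothelium that covers epididymal fat were abundant in libraries labelled subcutaneous and nearly missing in those labelled visceral. Upk3b, a uroplakin of the mesothelium, was at 92.4 ± 58.8 TPM in the 20 libraries labelled subcutaneous and 0.115 ± 0.166 TPM in the 20 labelled visceral. Wt1, a transcription factor of the mesothelium and of visceral fat precursors, was at 3.704 ± 1.857 and 0.011 ± 0.015 TPM, and Msln, which encodes mesothelin, was at 35.7 ± 19.0 and 0.442 ± 0.228 TPM. Positional genes typical of inguinal (subcutaneous) fat showed the opposite. Shox2 was at 0.794 ± 0.309 TPM in libraries labelled subcutaneous and 13.0 ± 4.31 TPM in those labelled visceral. Tbx15 was at 0.021 ± 0.023 and 2.58 ± 1.13 TPM, and Hoxc10 was at 2.11 ± 1.75 and 32.9 ± 8.30 TPM. Ucp1, the uncoupling protein of thermogenic fat cells, had medians of 0.183 and 1.47 TPM; its means of 0.807 and 11.4 TPM were each carried by 1 library, at 12.1 and 192 TPM. The epididymal and mesothelial list of 17 genes scored 2.29 to 4.05 (mean log2) in libraries labelled subcutaneous and 0.63 to 1.46 in those labelled visceral, with no overlap. The inguinal list of 12 genes scored 0.89 to 1.78 and 2.12 to 3.11. Titles ended in e or ewat, an abbreviation used for epididymal fat, for the 20 libraries labelled subcutaneous, and in i for the 20 labelled visceral.

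**Figure D1:**
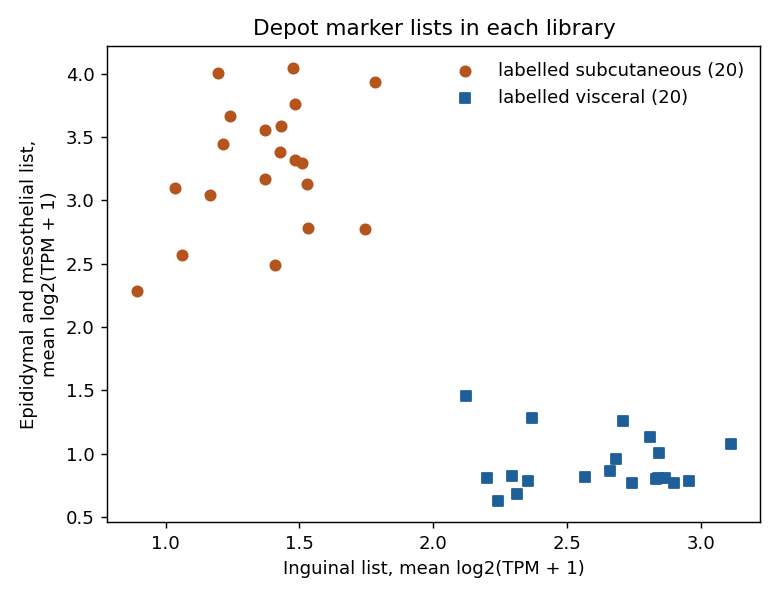
Each point is 1 of 40 libraries, with its score on the inguinal list on the x axis and on the epididymal and mesothelial list on the y axis (mean log2(TPM + 1) over the list). Libraries labelled subcutaneous lie between 2.29 and 4.05 on the y axis and those labelled visceral between 0.63 and 1.46.

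Transcripts of other tissues were unevenly spread over the libraries. A list of epididymis and testis genes summed to over 500 TPM in 7 libraries labelled subcutaneous. It reached 39530 TPM in normal with drug library 9, 11434 TPM in HFD with drug library 27 and 674 to 4581 TPM in the other 5. A list of B cell and plasma cell genes summed to over 1000 TPM in 10 libraries labelled visceral. These were HFD library 23, HFD with drug libraries 25, 26 and 27, normal libraries 94, 96 and 99, and normal with drug libraries 6, 8 and 9. Skeletal muscle genes summed to 69.7 to 22405 TPM in libraries labelled visceral, highest in HFD with drug library 62, where mitochondrially encoded genes took 43.5% of TPM against 20.3 to 34.0% in the other 39. No pair of libraries was identical.

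**Figure D2:**
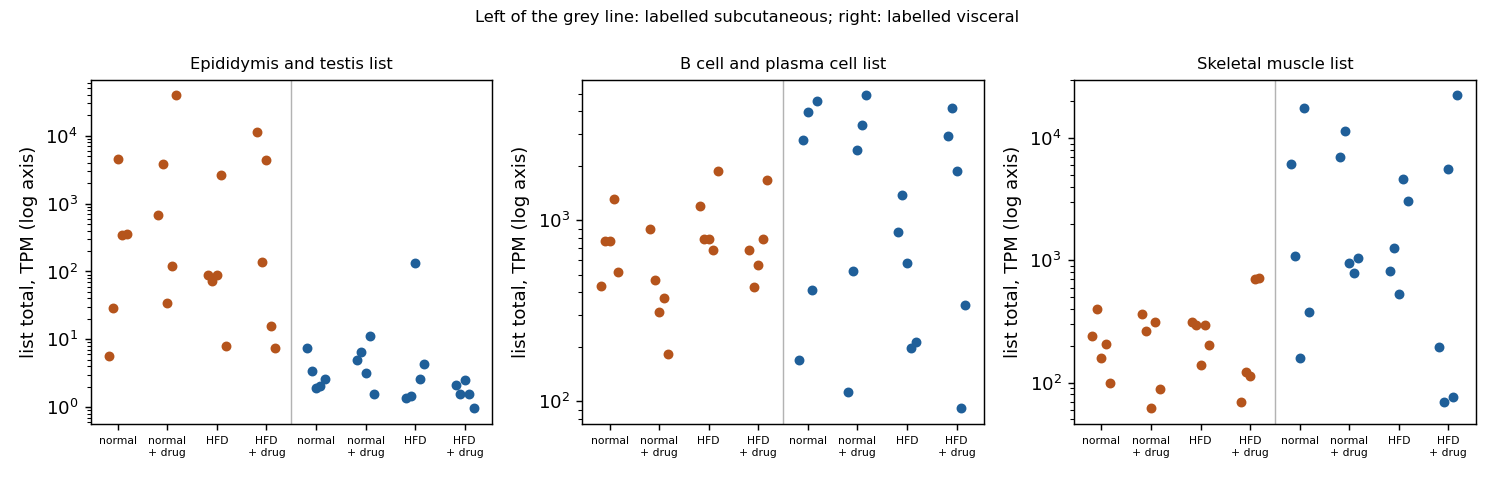
Total TPM (log axis) of the epididymis and testis, B cell and plasma cell, and skeletal muscle lists, with 1 point per library and 5 libraries per group. Epididymis and testis genes reach 39530 TPM in a library labelled subcutaneous, and muscle genes reach 22405 TPM in a library labelled visceral.

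The first comparison asked what HFD changed in fat labelled subcutaneous. Lep, genes of the lipogenesis list and genes of the lipid-associated macrophage list were higher with HFD, and Cfd and Gpx3 were lower. Lep, which encodes the satiety hormone leptin, was at 1166 ± 588 TPM with HFD and 106.5 ± 46.2 TPM with normal diet (log2 change 3.36, SE 0.526, adjusted p = 0.000977). Sfrp5, a secreted Wnt inhibitor of fat cells, rose from 58.3 ± 39.4 to 828 ± 205 TPM (log2 change 4.04, SE 0.535, adjusted p = 0.000313). Gpx3, a secreted glutathione peroxidase, fell from 1931 ± 275 to 622.5 ± 243 TPM (log2 change -1.72, SE 0.391, adjusted p = 0.0115). In each of these 3 genes the 5 HFD libraries did not overlap the 5 normal libraries. In all, 799 of 7776 genes passed the threshold, 511 higher and 288 lower. Groups did not overlap in 1239 genes (15.9%), where chance gives 2 of 252 splits.

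Other large increases in the same comparison were those of Ubd, a ubiquitin-like protein induced by cytokines (log2 change 3.37, adjusted p = 0.00194), Prr32 (2.65, 0.00245), Prelp, a matrix proteoglycan (2.11, 0.00154), and Lgals3, a galectin of macrophages (2.03, 0.0169). Decreases included Cfd, which encodes the adipokine adipsin (from 33830 ± 5784 to 9733 ± 7251 TPM, log2 change -2.29, adjusted p = 0.0156), and the cytochrome Cyp2e1 (-2.34, 0.0229). Others were Gadd45g, a stress response gene (-1.68, 0.00903), B3galt2 (-1.64, 0.0127) and Pck1, an enzyme of glycerol synthesis in fat cells (-1.60, 0.021). The calls of Lgals3, Cfd, Pck1 and Cyp2e1 ended without HFD library 22 or 50 (Cyp2e1 also without normal library 91), with adjusted p-values of 0.0602, 0.0536, 0.0702 and 0.0775 without HFD library 22.

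Of 19 tested genes of the lipid-associated macrophage list, 9 rose with HFD and none fell in libraries labelled subcutaneous (13 rose when adjusted over the list alone), with a median log2 change of 1.28. The list passed camera (adjusted p = 2.56e-06), a call that was lost at adjusted p = 0.865 with an estimated correlation. The number of genes that rose was 3 without HFD library 22 or 50. Members of the list included the lysosomal proteases Ctsd (log2 change 1.47, SE 0.259, adjusted p = 0.00217), Ctsl (1.17, 0.00824) and Ctsb (1.25, 0.0125). Itgax, which encodes the integrin CD11c, was at 75.3 ± 88.0 TPM with HFD and 6.16 ± 1.18 TPM with normal diet (log2 change 2.44, adjusted p = 0.0188). Trem2, a lipid receptor of macrophages, was at 122 ± 133 and 13.2 ± 2.96 TPM (2.31, 0.0218). Ccl2, a monocyte attractant, was at 104 ± 53.0 and 32.1 ± 4.90 TPM (1.54, 0.0318). Macrophage transcripts were uneven among the HFD libraries: Gpnmb, a lysosomal glycoprotein of these cells, was at 701 TPM in library 22, 899 TPM in library 50 and 44.4 to 83.9 TPM in the other 3. Without HFD library 22 or 50 the calls of Trem2 and Ccl2 ended (adjusted p up to 0.0739 and 0.103), as did that of Ccl2 without normal library 91, 92, 96 or 99. With no filter the adjusted p-values of Itgax, Trem2 and Ccl2 were 0.0562, 0.0676 and 0.0975.

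Further lists fixed beforehand passed camera in this comparison. Of 21 extracellular matrix genes, 4 rose (7 adjusted over the list alone; camera adjusted p = 0.00109; adjusted p = 0.892 with an estimated correlation). Among them was Col6a2, a chain of collagen VI (208.5 ± 68.2 against 76.37 ± 10.99 TPM, log2 change 1.39, adjusted p = 0.00729). Col1a1 did not pass (0.84, adjusted p = 0.129). Of 7 MHC class II genes, 3 rose (6 adjusted over the list alone; camera adjusted p = 0.00152; adjusted p = 0.865 with an estimated correlation). Of 17 lipogenesis genes, 7 rose (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0233; adjusted p = 0.865 with an estimated correlation). This call was lost without HFD library 23 or normal library 91 (adjusted p up to 0.129). Without HFD library 22 or 50 the number that rose was 1 in the matrix list and 1 in the MHC class II list, and without normal library 96 it was 2 and 1. It was 2 in the matrix list without normal library 92, 98 or 99, and in the lipogenesis list 3 without HFD library 22 and 4 without normal library 91. Dgat2, which completes triglyceride synthesis, was at 151 ± 42.7 and 37.6 ± 15.8 TPM (log2 change 2.05, adjusted p = 0.00133), and Gpd1, which makes glycerol phosphate, changed by 1.99 (0.00152). Fasn, the fatty acid synthase, was at 493 ± 197 and 163 ± 43.0 TPM (1.52, 0.0159); its call ended without HFD library 22 (adjusted p = 0.0571) and with no filter (0.0511). The epididymal and mesothelial list was lower with HFD by camera (median -0.58, none of 8 genes past the threshold, 3 adjusted over the list alone, adjusted p = 0.0233; adjusted p = 0.865 with an estimated correlation). It was not called without HFD library 50 or normal library 91 (adjusted p up to 0.105). Adipoq, which encodes adiponectin, and the desaturase Scd1 did not pass (log2 changes 0.10 and 0.56, adjusted p = 0.895 and 0.338).

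Bco1, Bco2 and Rarb were near the floor in these libraries. The carotenoid cleavage enzymes Bco1 and Bco2 averaged 0.311 and 0.626 TPM with HFD and 0.329 and 0.656 TPM with normal diet, and the retinoic acid receptor gene Rarb averaged 0.0329 and 0.0310 TPM. Ucp1 averaged 0.191 and 0.201 TPM; in the fit with no filter these 4 genes had an adjusted p = 1. Cyp26b1, which degrades retinoic acid, was below the filter and lower with HFD in the fit without it (2.26 against 7.42 TPM, log2 change -1.33, adjusted p = 0.0167). Adgre1, the macrophage marker F4/80, was also below the filter (19.1 against 4.50 TPM, 1.48, adjusted p = 0.0766). The number of genes past the threshold fell to 302, 381, 423, 512 and 454 without HFD libraries 22 and 50 and normal libraries 91, 96 and 99.

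**Figure D3:**
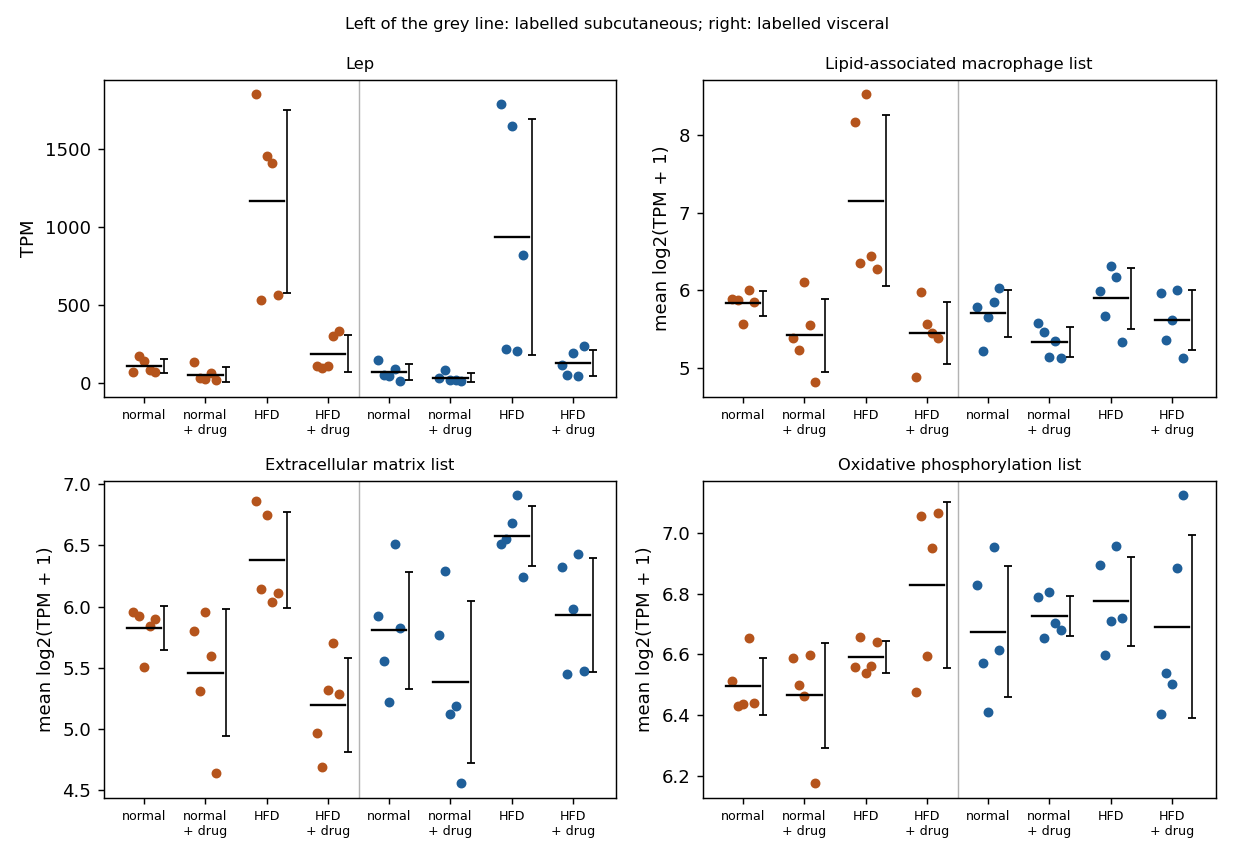
Lep in TPM and the scores (mean log2(TPM + 1)) of the lipid-associated macrophage, extracellular matrix and oxidative phosphorylation lists in the 8 groups, with groups labelled subcutaneous left of the grey line. Points are libraries, lines means and bars SD (n = 5). Among libraries labelled subcutaneous, the macrophage list scores 6.27 to 8.53 with HFD and 4.88 to 5.98 with HFD and drug.

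The second comparison asked what the drug changed under HFD in fat labelled subcutaneous. Macrophage and extracellular matrix transcripts were lower with the drug, as were Lep, Dgat2 and Gpd1, and 5 of 24 oxidative phosphorylation genes and the keratins Krt8 and Krt18 were higher. Gpnmb was at 13.5 ± 6.35 TPM with drug and 357 ± 411 TPM without (log2 change -3.65, SE 0.679, adjusted p = 0.00303). Lep was at 188 ± 116 and 1166 ± 588 TPM (-2.66, SE 0.526, adjusted p = 0.00344). The 2 groups of 5 overlapped in neither gene. Col1a1, the main chain of collagen I, was at 123 ± 56.9 and 334 ± 138 TPM (-1.47, SE 0.345, adjusted p = 0.00682). Cox4i1, a subunit of cytochrome oxidase, was at 508 ± 45.0 and 307 ± 19.5 TPM (0.72, SE 0.122, adjusted p = 0.00208). In all, 2129 of 7776 genes passed the threshold, 342 higher and 1787 lower, and 1363 genes (17.5%) did not overlap. The median change of all genes was -0.187, against -0.015 after quantile normalization (545 higher and 890 lower) and 0.016 with library medians made equal (753 higher and 906 lower). With the gene length trend removed it was 0.035 (681 higher and 760 lower), and with that trend removed and library medians kept it was -0.185 (214 higher and 1646 lower). With the length trend removed and the covariate for epididymis transcripts the balance turned (1001 higher and 982 lower).

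The macrophage genes that fell with the drug under HFD in libraries labelled subcutaneous spanned several functions. Of 19 lipid-associated macrophage genes, 13 fell and none rose (15 fell adjusted over the list alone; median log2 change -1.40; camera adjusted p = 0.000138; adjusted p = 0.653 with an estimated correlation). Of 17 general macrophage genes, 13 fell (14 adjusted over the list alone; median -1.18; camera adjusted p = 0.000748; adjusted p = 0.653 with an estimated correlation). The number that fell was 5 without HFD library 22 or 50 and 7 without HFD with drug library 27. All 7 tested MHC class II genes fell (7 adjusted over the list alone; median -1.04; camera adjusted p = 0.00165; adjusted p = 0.653 with an estimated correlation). Itgax was at 3.45 ± 0.873 TPM with drug (log2 change -3.13, adjusted p = 0.00342). Trem2 was at 9.01 ± 4.84 TPM (-2.92, 0.00398) and Ccl2 at 26.9 ± 13.5 TPM (-1.94, 0.0052). Mpeg1, a pore-forming protein of macrophages, was at 257 ± 36.3 and 1496 ± 1194 TPM (-2.17, 0.00398). Lgals3 changed by -2.13 (0.00684) and the lysosomal protease Ctss by -2.09 (0.00417). Others were the Fc receptor gene Fcgr1 (-1.75, 0.00374), the oxidase subunit Cybb (-1.76, 0.00401) and H2-Ab1, a chain of MHC class II (-1.07, 0.0061). Of 13 cytokine and chemokine genes, 5 fell (7 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.094). A further fit left out all 7 libraries rich in epididymis transcripts, 3 of them among these 10. There the general and lipid-associated macrophage lists both had a camera adjusted p = 0.0624, with medians of -1.10 and -1.25. With no filter, Adgre1 was lower with drug (3.68 against 19.1 TPM, -1.71, adjusted p = 0.0205).

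Of 21 extracellular matrix genes, 20 fell with the drug under HFD in libraries labelled subcutaneous (20 adjusted over the list alone), with a median log2 change of -1.33 (camera adjusted p = 1.87e-07; adjusted p = 0.653 with an estimated correlation). They included Col6a3 and Col6a2, chains of collagen VI (-1.62 and -1.53, adjusted p = 0.00313 and 0.00322), and Tgfb1, a growth factor that drives matrix production (19.0 ± 2.68 against 49.8 ± 20.9 TPM, -1.26, adjusted p = 0.00208). Pdgfrb, a receptor of pericytes and fibroblasts, changed by -1.11 (adjusted p = 0.0042) and Tie1, a receptor of endothelial cells, by -1.05 (0.00698). Of 12 fibroblast genes, 4 fell and 1 rose, and of 7 endothelial genes, 3 fell (4 and 1, and 4, adjusted over the list alone); neither list passed camera (adjusted p = 0.466 and 0.0772). Of 12 immediate early genes, 4 fell (9 adjusted over the list alone; camera adjusted p = 0.0666), among them Egr1 (-1.99, 0.00996) and Fos (-1.85, 0.0133).

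Fat cell transcripts changed in part. Sfrp5 was at 194 TPM with drug (log2 change -2.10, adjusted p = 0.0101) under HFD in libraries labelled subcutaneous. Dgat2 changed by -1.51 (0.00523), Gpd1 by -1.44 (0.0064), the peptide hormone gene Apln by -1.58 (0.00344) and Npr3, a clearance receptor for natriuretic peptides, by -1.52 (0.00441). Inhbb, which encodes a subunit of activin and inhibin, was at 42.2 ± 11.9 and 105 ± 19.0 TPM (-1.33, SE 0.197, adjusted p = 0.00192). G6pdx, which supplies NADPH for fat synthesis, changed by -0.74 (0.00502), and of 17 lipogenesis genes 4 fell (4 adjusted over the list alone). Adipoq, Fasn and Scd1 did not pass (log2 changes -0.12, -0.83 and -0.19, adjusted p = 0.819, 0.103 and 0.717). Gpx3 was at 2700 ± 1778 TPM with drug (1.95, SE 0.391, adjusted p = 0.00382), and Sephs2, an enzyme of selenium supply, was at 234 and 122 TPM (adjusted p = 0.00856). Gsta4, a glutathione transferase, changed by 1.38 (adjusted p = 0.0046).

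Of 24 oxidative phosphorylation genes, 5 rose with the drug under HFD in libraries labelled subcutaneous and none fell (5 adjusted over the list alone). The median log2 change was 0.20 (camera adjusted p = 2.43e-07; adjusted p = 0.653 with an estimated correlation). The list score overlapped between the groups (6.48 to 7.07 with drug, 6.54 to 6.66 without) and did not pass (exact permutation p = 0.143, adjusted 0.265). The number that rose was 8 without HFD with drug library 27 and 3 without library 25 of that group. With the gene length trend removed, 8 rose (median 0.34; camera adjusted p = 1.97e-06; adjusted p = 0.437 with an estimated correlation). With that trend removed and library medians kept, 4 rose (median 0.115; camera adjusted p = 2.28e-05; adjusted p = 0.637 with an estimated correlation). Ndufa1, a subunit of complex I, was at 121 and 72.1 TPM (0.73, adjusted p = 0.0103), and Atp5c1, a subunit of ATP synthase, changed by 0.49 (0.0153). With the drug, Calml3, a calmodulin-like protein of epithelia, was at 370 ± 254 against 7.49 ± 4.26 TPM (5.03, SE 1.201, adjusted p = 0.00736). Krt18 was at 233 ± 198 against 9.504 ± 4.419 TPM (3.92, 0.00557), Krt8 at 112 ± 75.4 against 6.68 TPM (3.42, 0.00615) and Gstm7 at 494 ± 548 against 10.3 TPM (4.26, 0.0155). Cd24a, a surface glycoprotein of epithelia and blood cells, changed by 2.41 (0.00903). The epididymal and mesothelial list passed camera as higher (3 of 8 genes rose, the keratins Krt8, Krt18 and Krt19; 3 adjusted over the list alone; adjusted p = 0.00132; adjusted p = 0.653 with an estimated correlation). In the same groups the epididymis and testis list had a median change of 2.55, with none of 6 genes past the threshold (camera adjusted p = 0.042; adjusted p = 0.653 with an estimated correlation; 0.267 after quantile normalization). The call was also lost without HFD library 23 or 83 (adjusted p up to 0.085).

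Genes of carotenoid and vitamin A handling did not move as a list with the drug under HFD in libraries labelled subcutaneous (1 higher and 2 lower of 14; 1 and 3 adjusted over the list alone; camera adjusted p = 0.753). Scarb1, a receptor that takes up lipoprotein lipids and carotenoids, was at 10.9 and 20.7 TPM (log2 change -0.88, SE 0.167, adjusted p = 0.00313). Dhrs3, which reduces retinal to retinol, was at 32.8 and 69.9 TPM (-1.01, SE 0.237, adjusted p = 0.00674). Of 8 retinoic acid target genes, 3 fell (3 adjusted over the list alone; camera adjusted p = 0.189). Bco1, Bco2, Rarb, Cyp26b1 and Ucp1 were below the filter, and in the fit without it their log2 changes were -0.20, 0.17, -0.02, 0.46 and 0.14 (adjusted p = 0.672, 0.583, 0.327, 0.401 and 0.957). The number of genes past the threshold was 1210 and 1218 without HFD libraries 22 and 50 and 1255 without HFD with drug library 25.

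On the normal diet, the drug changed no gene past the threshold in libraries labelled subcutaneous. Lep was at 53.4 ± 48.6 TPM with drug and 106.5 ± 46.2 TPM without (log2 change -1.28, adjusted p = 0.749). Itgax changed by -0.73 (0.824), Trem2 by -0.60 (0.842), Ccl2 by 0.05 (0.983), Col1a1 by -0.34 (0.847), Adipoq by -0.45 (0.818), Fasn by 0.47 (0.821) and Scd1 by -0.58 (0.77). By limma, 0 of 7776 genes passed, with 504 at an unadjusted p under 0.05; groups did not overlap in 90 genes (1.16%), close to the share chance gives. Camera called 13 lists, among them MHC class II (median -0.61, none of its genes past the threshold, 3 adjusted over the list alone, adjusted p = 0.000155) and extracellular matrix (median -0.43, adjusted p = 0.000334). With an estimated correlation none of the 13 remained (adjusted p = 0.36 to 0.708), and 10 of them were lost with a covariate for epididymis transcripts, which reached 39530 TPM in 1 of these libraries.

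Whether the drug changed fat labelled subcutaneous more under HFD than under normal diet was tested as an interaction, and 1 gene passed, Inhbb. Its means were 42.2 ± 11.9 TPM with HFD and drug, 105 ± 19.0 TPM with HFD, 75.9 TPM with normal diet and drug and 52.6 ± 11.2 TPM with normal diet (difference of log2 changes -1.85, SE 0.278, adjusted p = 0.0212). At an unadjusted p under 0.05 there were 1376 genes. Camera called the lipid-associated macrophage list as lower (median -1.14, 7 genes adjusted over the list alone, adjusted p = 0.00481), as well as extracellular matrix (-0.86, 1 gene adjusted over the list alone, 0.000172) and immediate early genes (-0.91, 7 genes adjusted over the list alone, 0.00244). Oxidative phosphorylation was called as higher (0.29, adjusted p = 2.83e-08). All of these calls were lost at adjusted p = 0.875 with an estimated correlation, and the macrophage list had an adjusted p = 0.11 without the epididymis-rich libraries and 0.074 without HFD with drug library 27. The count was 0 without HFD library 22 or 50, HFD with drug library 27, normal with drug library 8 or normal library 92, 96 or 99. It was 367 with a covariate for epididymis transcripts (33 higher and 334 lower), 188 with that covariate and the gene length trend removed, 0 without the epididymis-rich libraries, 15 without normal with drug library 9, 3 without HFD library 83 or normal library 98 and 2 without HFD with drug library 52.

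In fat labelled visceral, Lep, Inhbb and genes of the adipokine and matrix lists were higher with HFD, Dgat1 and Acsl1 were lower, and 1 of 18 lipid-associated macrophage genes passed. Lep was at 937 ± 760 TPM with HFD and 68.7 ± 51.7 TPM with normal diet (log2 change 3.63, SE 0.778, adjusted p = 0.00878). Inhbb was at 96.04 ± 38.54 and 19.7 ± 7.39 TPM (2.19, SE 0.286, adjusted p = 0.000519). Dgat1, an enzyme of triglyceride synthesis, was at 89.3 ± 19.4 and 249.8 ± 47.8 TPM (-1.48, SE 0.208, adjusted p = 0.000877). None of these 3 genes overlapped between the groups. Of 7760 genes, 693 passed, 489 higher and 204 lower, and 490 (6.31%) did not overlap. The balance turned with library weights (1619 higher and 1879 lower) and without the libraries rich in B cell transcripts, where 1 gene passed, as lower.

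The other large increases with HFD in libraries labelled visceral were those of Sfrp5 (594 ± 390 against 46.39 ± 24.97 TPM, log2 change 3.44, adjusted p = 0.00345) and Prelp (1055 ± 514 against 160 ± 79.9 TPM, 2.68, 0.00168). They were followed by Thbs1, a matrix glycoprotein (474.5 ± 109 against 105 ± 99.8 TPM, 2.64, 0.00454), and Cavin3, a caveola protein (441 against 107.5 TPM, adjusted p = 0.00287). Ubd changed by 2.08 (0.0409), a call lost without HFD library 22 or 50 or any normal library (adjusted p up to 0.125). Decreases included Cyp2e1 (1437 against 4516 TPM, -1.86, 0.00386), Acsl1, which activates fatty acids (122 ± 26.4 against 347 ± 61.7 TPM, -1.51, 0.0052), B3galt2 (-1.60, 0.00413), Sephs2 (-1.17, 0.00216) and Cat, the catalase gene (372 against 797.5 TPM, -1.12, 0.00568). Of 23 extracellular matrix genes, 4 rose (6 adjusted over the list alone; median 0.85; camera adjusted p = 5.02e-05; adjusted p = 0.901 with an estimated correlation), with Bgn, a matrix proteoglycan, at 0.87 (adjusted p = 0.00568). Acta2, the smooth muscle actin gene, changed by 1.70 (0.00816). Of 16 adipokine genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0115; adjusted p = 0.901 with an estimated correlation), with Apln at 45.4 against 8.11 TPM (2.46, 0.00243). Of 14 carotenoid and vitamin A genes, 4 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0137; adjusted p = 0.901 with an estimated correlation). The aldehyde dehydrogenase Aldh1a7 was at 54.3 against 15.0 TPM (1.77, 0.00251). This list call was lost without HFD library 22 or normal library 99 (adjusted p up to 0.0628). Of 12 immediate early genes, 3 rose (3 adjusted over the list alone; camera adjusted p = 0.0115; adjusted p = 0.901 with an estimated correlation), with Fos at 2.05 (0.00905). Without HFD library 22 or 50 or normal library 94, 96 or 99, the number that rose was 1 in the carotenoid list and 1 in the immediate early list. In the carotenoid list it was also 2 without HFD library 51 or 83 and 7 without HFD library 23, and the number that fell was 2 without library 51. The adipokine gene that fell was not called without HFD library 22 or 50 or any 1 of the normal libraries. Npr3 changed by 2.82 (0.00192) and Pde3b, which degrades cyclic AMP, by -0.91 (0.0118).

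Few macrophage and lipogenesis genes passed with HFD in libraries labelled visceral. Itgax was at 6.12 with HFD and 6.95 TPM with normal diet (log2 change -0.13, adjusted p = 0.883). Trem2 changed by 0.41 (0.627), Ccl2 by 1.03 (0.282), Col1a1 by 0.99 (0.248), Fasn by -0.05 (0.944), Scd1 by 0.92 (0.0551), Adipoq by 0.36 (0.367) and Cyp26b1 by -0.96 (0.0733). Of 18 lipid-associated macrophage genes, 1 rose (1 adjusted over the list alone), and camera gave an adjusted p = 0.0851. Of 17 lipogenesis genes, 1 rose (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.314). B cell genes had a median change of -2.50 (none of 11 past the threshold; camera adjusted p = 0.0348, lost in 6 of 10 fits that left out 1 library; adjusted p = 0.901 with an estimated correlation). The adipokine and carotenoid lists were lost with a covariate for B cell transcripts (adjusted p = 0.201 and 0.214). The fit without libraries rich in B cell transcripts left out all 10 of them under this label, with 4 HFD and 2 normal libraries left. The shared spread was thus also estimated from fewer libraries. In that fit 1 gene passed, Lep had a change of 2.85 (adjusted p = 0.265) and the matrix list an adjusted p = 0.0725. The number of genes past the threshold was 269 and 245 without HFD libraries 22 and 50 and 326, 360 and 357 without normal libraries 94, 96 and 99.

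With the drug under HFD in libraries labelled visceral, Thbs1, Apln and Inhbb were lower, as were 3 of 7 endothelial and 2 of 23 matrix genes, in calls that rested on few libraries. Thbs1 was at 67.5 ± 23.5 TPM with drug and 474.5 ± 109 TPM without (log2 change -2.82, SE 0.498, adjusted p = 0.0153). Apln was at 6.84 ± 1.44 and 45.4 ± 22.4 TPM (-2.44, SE 0.417, adjusted p = 0.0149) and Inhbb at 31.67 and 96.04 TPM (-1.49, SE 0.286, adjusted p = 0.0173). Of 7760 genes, 402 passed, 11 higher and 391 lower, and 373 (4.81%) did not overlap. The slope of expression on exon length was -0.023 ± 0.101 per doubling with drug and 0.124 ± 0.091 without (exact permutation p = 0.0476). The split of calls was 10 higher and 44 lower with mitochondrial genes removed and 7 higher and 24 lower with the gene length trend removed. After quantile normalization 1 gene passed. The count was 0 without HFD library 22, 4 without HFD library 50, 75 without HFD library 83, 853 without HFD library 23, and 245, 64, 156 and 25 without HFD with drug libraries 25, 26, 27 and 62.

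Among the other genes that were lower with the drug under HFD in libraries labelled visceral were Ccn1 (log2 change -2.03, adjusted p = 0.0221), Npr3 (-1.99, 0.0283) and Cavin3 (-1.46, 0.0321). So were Apoa2 (-4.48, 0.0381), Alb (-2.67, 0.0361) and Ttr (-3.42, 0.0448), which encode plasma proteins made in the liver. Alb was at 62.2, 133, 632, 255 and 44.7 TPM in HFD libraries 22, 23, 50, 51 and 83. None of these 6 genes was called after quantile normalization or without HFD library 22 or 50. With 1 library left out, Ttr was below the filter in 4 of 10 fits and was not called in the other 6. Ccn1, Npr3, Cavin3, Apoa2 and Alb were also not called without HFD with drug library 26, and all of these but Ccn1 not without library 62. Apoa2 and Alb were not called without HFD library 51 or HFD with drug library 27 or 54 either, and Npr3, Cavin3 and Apoa2 not without HFD library 83. Of 7 endothelial genes, 3 fell (7 adjusted over the list alone; median -0.50; camera adjusted p = 0.000327; adjusted p = 0.851 with an estimated correlation). The tight junction gene Cldn5 was at 576 against 1339 TPM (-1.16, 0.0173) and Tie1 changed by -0.65 (0.0236). Of 12 immediate early genes, 3 fell (6 adjusted over the list alone; camera adjusted p = 0.00398; adjusted p = 0.851 with an estimated correlation), with Dusp1 at -1.08 (0.0237). Of 23 matrix genes, 2 fell (6 adjusted over the list alone; camera adjusted p = 0.00602; adjusted p = 0.979 with an estimated correlation). Of 14 carotenoid and vitamin A genes, 3 fell (9 adjusted over the list alone; camera adjusted p = 0.00398; adjusted p = 0.851 with an estimated correlation). Both list calls were lost with the B cell covariate (0.554 and 0.188), and the matrix call also without HFD with drug library 26 (0.0973). Without HFD library 22 or 50, 0 genes fell in each of these 4 lists. Without HFD library 23 the number was 5 in the endothelial and matrix lists and 6 in the carotenoid list. Without HFD library 83 it was 1 in the endothelial, matrix and immediate early lists and 0 in the carotenoid list. With 1 HFD with drug library left out, the endothelial list had 1 without library 26 and 0 without 62, and the matrix list had 1 without 26, 27 or 62. The carotenoid list had 0 without library 25, 26, 27 or 62 and 1 without 54, and the immediate early list had 0 without 26 or 62 and 1 without 25, 27 or 54. B cell and T cell genes had median changes of 2.68 and 2.06, with none of 11 and 9 past the threshold (camera adjusted p = 0.000327 for both; adjusted p = 0.851 with an estimated correlation). Lep was at 126 and 937 TPM (-2.65, adjusted p = 0.0556), and Ccl2, Fasn, Scd1, Col1a1, Itgax, Trem2 and Adipoq changed by -1.52, -0.89, -0.61, -0.77, 0.11, -0.56 and -0.51 (adjusted p = 0.141, 0.178, 0.229, 0.426, 0.923, 0.568 and 0.249).

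On the normal diet, the drug changed no gene past the threshold in libraries labelled visceral. Lep was at 32.4 and 68.7 TPM with and without drug (log2 change -0.97, adjusted p = 0.999), Fasn at 522 ± 264 and 239 ± 72.2 TPM (1.04, 0.999), and Trem2 changed by -0.93 (0.999). By limma, 0 of 7760 genes passed, 284 had an unadjusted p under 0.05, and 70 (0.9%) did not overlap. Camera called 7 lists, among them lipogenesis as higher (median 0.15, adjusted p = 4.39e-05) and extracellular matrix as lower (-0.42, 0.00165; lost without normal library 98 or normal with drug library 9, adjusted p up to 0.887). With an estimated correlation none passed (adjusted p = 0.429 to 0.973), and all 7 were lost without the libraries rich in B cell transcripts. The drug-by-diet interaction in libraries labelled visceral also called 0 genes by limma (409 at an unadjusted p under 0.05, smallest adjusted p = 0.731). Lipogenesis was lower by camera (median -0.48, adjusted p = 2.91e-05; adjusted p = 0.39 with an estimated correlation).

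The changes with drug under HFD ran mostly against the changes with HFD under both labels. Lep, Sfrp5, Dgat2, Gpd1 and Inhbb all rose with HFD and fell with the drug in libraries labelled subcutaneous. Of the 799 genes called with HFD there, 86.9% had the opposite sign with the drug (92.4% of the higher and 77.1% of the lower calls), and 345 rose and then fell past both thresholds, where independent calls would give 117.4. In libraries labelled visceral the share was 98.4% of 693, and 244 genes rose and then fell past both thresholds, against 24.6. Libraries rich in B cell transcripts numbered 3 of 5 with normal diet, 1 of 5 with HFD and 3 of 5 with HFD and drug under this label, and the B cell list scored 4.14, 2.04 and 4.06, so this imbalance followed the same order. With a covariate for B cell transcripts the share was 98.6% of 623, and 125 genes rose and then fell, against 10.8. Without the rich libraries 1 gene was called with HFD and 19 with the drug, and none rose and then fell. Under the label subcutaneous the share was 88.0% of 1411 with a covariate for epididymis transcripts and 78.0% of 952 without the libraries rich in them. Both comparisons used the same HFD libraries, which makes opposite signs common by chance. The counts given for independent calls ignore this, and the simulations did not count genes that rose and then fell. The excess over those counts therefore does not by itself show a reversal. In 100 simulations with no drug change the share had a median of 66.3% (13.6 to 92.3%) in libraries labelled subcutaneous, with 7 at or above the measured share. In those labelled visceral the median was 65.0% (17.0 to 96.1%), with 0 at or above it. With the HFD libraries split so that each comparison had its own, the median shares were 92.4% and 96.2%. Over all genes, which are not independent replicates, changes with HFD and with drug had r = -0.594 and r = -0.9, against simulated medians of -0.249 and -0.193, with 1 and 0 of 100 simulations at or below the measured r. With the covariates r was -0.673 and -0.766, and without the rich libraries -0.588 and -0.75.

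On the normal diet, libraries labelled subcutaneous and visceral differed in depot and muscle transcripts. Tcf21, a transcription factor of visceral fat precursors, was at 28.01 ± 6.475 TPM in libraries labelled subcutaneous and 0.0652 ± 0.0899 TPM in those labelled visceral (log2 change 4.74, SE 0.205, adjusted p = 1.25e-18). Hoxc10 was at 1.316 and 36.3 TPM (-4.02, adjusted p = 1.15e-09). Agt, which encodes angiotensinogen, was at 181 ± 12.03 and 16.9 ± 7.98 TPM (3.45, SE 0.47, adjusted p = 6.43e-06). Myh4, a myosin of fast skeletal muscle, was at 1.20 and 795 ± 1160 TPM (-6.85, SE 1.601, adjusted p = 0.00574). Of 8799 genes, 792 passed, 565 higher and 227 lower in libraries labelled subcutaneous, and 998 (11.3%) did not overlap. The split was 663 and 465 after quantile normalization and 474 and 360 with the gene length trend removed. It was 1780 and 1709 with library weights, and it turned with the length trend removed and the covariates for epididymis and B cell transcripts (533 and 612).

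All 8 tested genes of the epididymal and mesothelial list were higher in libraries labelled subcutaneous on the normal diet (8 adjusted over the list alone; median log2 change 4.24; camera adjusted p = 2.31e-21; adjusted p = 6.04e-06 with an estimated correlation). Upk3b differed by 6.25 (3.15e-12) and Msln by 4.55 (2.52e-11). Of 6 inguinal genes, 4 were lower (median -1.86; camera adjusted p = 3.85e-07; adjusted p = 0.0358 with an estimated correlation), with Shox2 at -2.87 (4.08e-09) and Hoxa10 at -2.48 (0.000233). Of 12 skeletal muscle genes, 8 were lower (11 adjusted over the list alone; median -4.68; camera adjusted p = 8.14e-10; adjusted p = 0.412 with an estimated correlation). The number was 5 without normal library 98 labelled visceral. Atp2a1, Tnni2, Tcap, Tnnt3 and Mylpf differed by -6.01, -5.74, -5.63, -5.57 and -4.88 (adjusted p from 0.00569 to 0.00832). B and T cell genes had medians of -2.56 and -2.28, with none past the threshold and 8 of 9 T cell genes adjusted over the list alone (camera adjusted p = 0.000753 and 0.000171; adjusted p = 0.729 and 0.71 with an estimated correlation). Further genes higher in libraries labelled subcutaneous were Thbs1 (521 against 105 TPM, 2.71, 0.0001), Gstm5 (2.47, 0.000638) and the matrix protein Mgp (257 against 49.6 TPM, adjusted p = 5.3e-07). So were the peptide hormone gene Adm (2.23, 0.000573), Ear2 (1.77, 0.00169), the matrix protease Adamts1 (1.76, 0.00448) and Aldh1a3, which makes retinoic acid (2.29, 0.000573). Lower were Mmp3, another matrix protease (5.79 against 61.7 TPM, -3.10, 1.21e-06), Gpd1 (76.9 against 327 TPM, -2.05, 5.73e-05), the glucose transporter Slc2a4 (-1.38, 0.00138) and the neutrophil gene S100a9 (2.30 against 36.8 TPM, -3.17, 0.00259). Without the libraries rich in B cell or epididymis transcripts 333 genes passed, and Thbs1, Gstm5 and Adamts1 did not (adjusted p = 0.0719, 0.078 and 0.0709). The count was 472 and 474 without libraries 91 and 92 labelled subcutaneous and 522 and 464 without libraries 96 and 99 labelled visceral.

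Whether diet and drug acted differently on the 2 labelled depots was tested as interactions over all 40 libraries. For HFD, 0 genes passed by limma (756 at an unadjusted p under 0.05, smallest adjusted p = 0.0947). The lipid-associated macrophage list changed more in libraries labelled subcutaneous (median 0.96, 5 genes adjusted over the list alone, camera adjusted p = 8.16e-06; adjusted p = 0.444 with an estimated correlation). For the drug under HFD, 16 genes passed, 9 higher and 7 lower, each at adjusted p = 0.0492, with 1764 at an unadjusted p under 0.05. The balance of higher and lower genes turned under several settings: 13 and 16 with a pseudocount of 0.5, 49 and 78 with quantile normalization, 311 and 550 with library weights, 79 and 114 with a random block for shared title numbers, 46 and 171 without mitochondrial genes and 55 and 85 with the length trend removed. It also turned in 7 fits that left out 1 library. Under the label subcutaneous these were 33 and 127 without HFD library 23, 31 and 66 without 82, 27 and 64 without 83, and 0 and 1 without HFD with drug library 27. Under the label visceral they were 0 and 1 without HFD library 83, 28 and 42 without HFD with drug library 54 and 51 and 170 without 62. The 2 genes named next were singled out after their values were seen. Cox6c, a subunit of cytochrome oxidase, was at 157 ± 18.5 TPM with HFD and drug and 86.9 ± 7.98 TPM with HFD in libraries labelled subcutaneous (difference of log2 changes 0.96). Psap, a lysosomal protein, was at 508 and 1539 TPM (-1.33). General macrophage genes changed more in libraries labelled subcutaneous (median -1.32, 12 genes adjusted over the list alone, camera adjusted p = 2.8e-06; adjusted p = 0.645 with an estimated correlation). So did lipid-associated macrophage genes (-0.96, 9 genes adjusted over the list alone, 5.71e-05). The MHC class II list differed by -1.48 (7 genes adjusted over the list alone, 5.78e-05). Both lists were at adjusted p = 0.645 with an estimated correlation. The MHC class II score fell with drug under the label subcutaneous (6.08 to 5.09) and rose under the label visceral (5.57 to 6.36, exact permutation p = 0.175). Libraries rich in B cell transcripts under the label visceral numbered 3 with HFD and drug and 1 with HFD. The calls of single genes did not hold with no filter, with a filter of 1 TPM or with the covariates (0 genes each). A fixed block for shared title numbers also left 0 genes. Leaving out 1 library gave counts from 0 to 221.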

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

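The interaction tests and the tests of lymph node tissue, of blood and of a single HFD library were set out before their results were seen; those of exchanged labels, carry-over, length and random regroupings were chosen after. Over 240 groups of 5, 20 had 1 library far from the other 4 by Dixon's criterion, where chance gives about 1 in 20.

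The first pattern was that depot markers ran against the depot labels. In 40 of 40 libraries both depot lists lay on the side of the other label, which is consistent with depot labels exchanged between the 2 tissues. Epididymis or mesothelium carried into samples that are otherwise inguinal fat would leave inguinal genes high, but the highest inguinal score among libraries labelled subcutaneous was 1.78, below the lowest (2.12) among those labelled visceral. The endings of the titles, e or ewat and i, also go with exchanged labels. Both labels hold the same strain and treatments, and a biological reversal of depot identity was not tested.

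The second pattern was the surplus of lower genes with drug under HFD in libraries labelled subcutaneous, and the lower macrophage and matrix transcripts within it. Genes called lower had a median exon length of 4739 bp, those called higher 1929.5 bp and genes not called 3255 bp, and the slope of expression on length was -0.053 ± 0.04 per doubling with drug and 0.048 ± 0.033 without (exact permutation p = 0.0159). Of the calls, 41.8% were lower in the fifth of genes with the shortest exons and 97.2% in the fifth with the longest, so a length trend between libraries may account for part of the surplus; removing the trend decided nothing, since the balance was set by whether library medians were kept (214 higher and 1646 lower) or not (681 and 760), and what set those medians was not tested. With the covariate for epididymis transcripts, 99% of calls recurred in the same direction, so these calls did not depend on it. With the length trend also removed, however, the covariate turned the balance, so a part of these transcripts in the surplus was not excluded. A further fit left out all 7 libraries rich in them, 3 of which were in the compared groups. There the macrophage list, at a median of -1.25, had a camera adjusted p = 0.0624 with fewer libraries. The macrophage list stayed lower with the length trend removed (median -1.09, or -1.31 with library medians kept) and with the covariate (-1.21). At least 11 of its genes were called with any 1 library left out. Each such fit kept HFD library 22 or 50, where the list scored 8.17 and 8.53, and no fit left out both. The other HFD libraries scored 6.27 to 6.45, above the 4.88 to 5.98 with drug. The size of the decrease may thus rest on libraries 22 and 50. These values leave the drug, fewer macrophages in the samples and unrecorded differences between the groups open.

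The third pattern was the uneven level of B and T cell transcripts among libraries labelled visceral. In HFD library 23 the B cell list scored 4.55 (1.38 to 1.49 in the other 4), the T cell list 3.62 (0.735 to 1.09) and the MHC class II list 6.49 (5.13 to 5.5). Over the 20 libraries, deviations from group means of a list of 5 lymph node vessel and stroma genes, none of them in another list and 3 of them at 0 TPM in at least 1 library, and of the B cell list had r = 0.984 and rho = 0.979 (permutation p = 1e-05 for both, the smallest that 100000 resamples can give, adjusted p = 2e-05 over 4 relations, r = 0.979 without the 2 farthest libraries). Ccl21a had a median of 572 and a maximum of 3843 TPM, Glycam1 27.7 and 247, Ccl19 30.5 and 169, Madcam1 2.49 and 7.12 and Chst4 0.414 and 3.31 TPM, which is consistent with lymph node tissue in some samples. Blood left in the tissue would raise erythrocyte genes with B cell genes, but they had r = -0.374 (permutation p = 0.11, rho = -0.462, permutation p = 0.042, adjusted 0.057, r = -0.322 without the 2 farthest); skeletal muscle genes had r = -0.455 (permutation p = 0.045, adjusted 0.06), rho = -0.376 (0.1) and r = -0.62 without the 2 farthest.

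Other single libraries stood apart from the other 4 of their group. Ucp1 was at 192 TPM in HFD with drug library 62 labelled visceral (others 0.312 to 4.27) and 12.1 TPM in normal with drug library 11 labelled subcutaneous (0.0526 to 0.305). Fasn was at 107 TPM in normal with drug library 2 labelled subcutaneous (235 to 303). Bco1 was at 1.22 TPM in HFD library 82 (0.0542 to 0.12) and 1.36 TPM in normal library 96 (0.0132 to 0.139), both labelled subcutaneous, and 0.136 TPM in normal library 94 labelled visceral (0.0298 to 0.0589). Normal library 96 labelled subcutaneous also had Col1a1 at 108 TPM (186 to 211), a matrix score of 5.51 (5.84 to 5.95) and a muscle score of 1.87 (1.21 to 1.4). Normal with drug library 5 labelled subcutaneous had a muscle score of 3.03 (0.999 to 1.42), and normal library 91 labelled subcutaneous an epididymal and mesothelial score of 4.01 (3.04 to 3.32). Among libraries labelled visceral, HFD with drug library 25 had an epididymal and mesothelial score of 1.26 (0.771 to 0.81), and library 26 of that group an inguinal score of 2.2 (2.71 to 2.84) and a carotenoid and vitamin A score of 2.94 (3.19 to 3.28). The epididymis and testis score was 2.06 in HFD library 50 (0.0785 to 0.25), 0.549 in normal with drug library 8 (0.118 to 0.242) and 0.446 in normal library 92 (0.126 to 0.216). Tests of a difference between groups passed for 1 gene (drug by diet, label subcutaneous) and 16 genes (depot by drug under HFD).

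Random regroupings of the same libraries numbered 100 per comparison with the real one included. In 5 comparisons no other regrouping gave as many genes as the real one. For the label subcutaneous these were HFD against normal (799 genes, highest other 2) and HFD with drug against HFD (2129, 6). For the label visceral they were HFD against normal (693, 550) and HFD with drug against HFD (402, 8). The last was the label subcutaneous against visceral (792, 19). Each is 1 of 100, so a random split of these libraries rarely gives such counts. A chance imbalance of carry-over between groups is not excluded by this, since the real grouping can hold it. For HFD against normal with the label visceral, 1 HFD and 3 normal libraries were rich in B cell transcripts. In the fit without all 10 rich libraries of that label, 1 gene passed. As many genes came from 3 of 100 for the drug-by-diet interaction with the label subcutaneous (1 gene, highest other 2). For depot by drug it was 2 of 100 (16 genes, highest other 22). Other regroupings thus gave more genes than the real one in both, and chance was not excluded for them. Leaving out 1 library gave 0 to 15 and 0 to 221 genes. For the 4 comparisons with 0 genes any split gives as many (100 of 100), which says nothing about chance: normal with drug against normal (highest other 1 and 1662), the interaction in libraries labelled visceral (1171) and depot by HFD (277). The highest values with the label visceral (550, 1662 and 1171) point to a structure of the samples. The split with 550 genes placed all 4 libraries rich in B cell transcripts in 1 arm, and that with 1662 genes placed 5 of 6 there. That with 1171 genes placed 2 in each HFD arm, and 1 and 5 in the arms of normal diet with and without drug.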

How the results depend on the processing

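Of the alternatives below, the filter of 1 TPM, the removal of mitochondrial genes, the carry-over covariate (epididymis or B cell transcripts), the removal of libraries rich in these transcripts, the removal of the gene length trend and the settings on library medians were chosen after the values were seen; the others were fixed before the data were examined. The following tally leaves out the fits without 1 library. Of 88 values under alternatives fixed beforehand, 52 were close to the main value and 36 were not. Of 74 under added ones, 46 were close and 28 were not. A count was taken as close if equal, which takes in 0 against 0, or within 1.5 times the main count. A share of opposed signs was taken as close within 1 SD of the simulated shares (17.9 and 18.7 percentage points, labels subcutaneous and visceral). Counts are of genes past the threshold, and the cause of a change was not tested unless given.

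In libraries labelled subcutaneous, HFD against normal (799) gave 384 with the stricter filter, which tests fewer genes, 1758 with library weights, 1356 with the 2 groups alone, 1411 with the covariate and 1797 with covariate and length removal together. HFD with drug against HFD (2129) gave 707 with the stricter filter and 3388 with a filter of 1 TPM, which tests more genes. Normal with drug against normal gave 0 throughout. The drug-by-diet interaction (1) gave 2 with a pseudocount of 5, quantile normalization or library weights, 0 with no filter, a filter of 1 TPM or without rich libraries, 367 with the covariate and 188 with covariate and length removal.

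In libraries labelled visceral, HFD against normal (693) gave 335 with the stricter filter, 3498 with library weights, 379 with the 2 groups alone, 1112 without mitochondrial genes and 1 without rich libraries, which leaves 4 against 2. HFD with drug against HFD (402) gave 87 with no filter, 195 with the stricter filter, 1 with quantile normalization, 1604 with library weights, 51 with the 2 groups alone, 54 without mitochondrial genes, 209 with the covariate, 19 without rich libraries, 31 with the length trend removed and 18 with length removal and covariate. Library weights gave 5 for normal with drug against normal (0) and 178 for the interaction (0), and a filter of 1 TPM gave 1 for the latter.

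For the labels subcutaneous against visceral (792) the counts were 1482 with no filter, 324 with the stricter filter, 3489 with library weights, 402 with title number as a fixed block (32 libraries), 1588 with a filter of 1 TPM, 1193 without mitochondrial genes and 333 without rich libraries. The depot-by-HFD interaction (0) gave 1 with no filter, either block, a filter of 1 TPM or without mitochondrial genes, 2 with the covariate, alone or with length removal, and 1153 with library weights. The depot-by-drug interaction (16) gave 29 with a pseudocount of 0.5 or the stricter filter, 5 with a pseudocount of 5, 0 with no filter, the fixed block, a filter of 1 TPM or the covariate, 127 with quantile normalization, 861 with library weights, 193 with the random block, 217 without mitochondrial genes, 2 without rich libraries, 140 with the length trend removed and 6 with length removal and covariate. Whether shared title numbers mark pairs was left open: over 16 numbers, deviations from group means correlated at a median r of 0.042 (-0.099 to 0.14, 3 over 0.1), 1 library matched its own number best, and the random block had a correlation of 0.122. Of 110 list calls, 2 held with an estimated correlation. Over all lists and comparisons fry called 21, which need not be among the 110. By exact permutation of list scores, no list passed for HFD against normal (smallest adjusted p = 0.0774 and 0.155, labels subcutaneous and visceral). None passed for HFD with drug against HFD with the label visceral (0.103). With the label subcutaneous, the general and lipid-associated macrophage, matrix, MHC class II, cell cycle, dendritic cell and epithelium lists passed (each 0.0442).

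Leaving out each library in turn gave 302 to 876 (HFD against normal), 1210 to 2053 (HFD with drug against HFD), 0 to 0 (normal with drug against normal) and 0 to 15 (interaction) for the label subcutaneous. For the label visceral the ranges were 245 to 1017, 0 to 853, 0 to 0 and 0 to 1, the last without HFD library 23. They were 464 to 926 between labels, 0 to 2 for depot by HFD (1 without HFD library 23 labelled subcutaneous, 2 without normal library 92 labelled visceral) and 0 to 221 for depot by drug, where each of the 20 libraries moved the count by over 1.5 times. Called members of the lipid-associated macrophage list, label subcutaneous, ranged from 3 to 10 higher with HFD and 11 to 13 lower with drug under HFD. The opposed share stayed at 83.8 to 93.0% and 96.4 to 99.7% with 1 library left out and at 78.0 to 92.4% and 96.2 to 100% under the alternatives, the 100% being of 1 gene. At this depth, genes under 10 TPM were mostly not tested. Planted changes of 0.5 on the log2 scale were called in 27.9% of cases (HFD against normal, label subcutaneous). For the drug-by-diet interaction with that label the share was 11.8%. The planned tests on read counts were not run.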

Other observations

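Epithelial transcripts were lower in HFD libraries labelled subcutaneous than with HFD and drug, and the difference from normal diet did not pass after adjustment. A list of skin and mammary epithelium genes, fixed beforehand, scored 0.557 ± 0.066 with HFD, 0.99 ± 0.197 with normal diet and 1.617 ± 0.92 with HFD and drug (mean log2, SD, n = 5). The difference had an exact permutation p = 0.00794 against normal diet (adjusted 0.0774 over the lists) and 0.00794 against HFD with drug (adjusted 0.0442), with no overlap in either case. Against HFD with drug the groups nearly met, at 0.6398 in HFD library 83 and 0.6412 in HFD with drug library 62. Several libraries with high scores also held epididymis transcripts. HFD with drug libraries 27 and 26 scored 2.73 and 2.46, with the epididymis and testis list at 11434 and 4471 TPM, and the other 3 of that group scored 0.641 to 1.16, with 7.39 to 138 TPM. Normal with drug library 9 scored 3.22, with 39530 TPM, while HFD library 82 scored 0.614, with 2618 TPM. Krt18, a keratin of simple epithelia and mesothelium, was at 6.02 to 15.7 TPM with HFD, 13.1 to 101 TPM with normal diet, 24.8 to 476 TPM with HFD and drug and 28.4 to 655 TPM with normal diet and drug. Calml3 was at 1.92 to 12.4 TPM with HFD, 13.4 to 435 TPM with normal diet and 22.7 to 741 TPM with HFD and drug.

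Plasma protein transcripts of the liver appeared in HFD libraries labelled visceral. In libraries 22, 23, 50, 51 and 83, Apoa2 was at 111, 122.5, 899, 396 and 37.7 TPM and Ttr at 13.2, 15.99, 110.5, 37.8 and 3.20 TPM, both highest in library 50. That library also had an epididymis and testis score above the other 4 of its group.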
